A study of Mus musculus with 4 samples.

How the data were processed

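The data are 4 libraries of messenger RNA from progenitor cells of mouse subcutaneous tissue, in 2 groups of 2: cells with floxed Gnas infected with Ad-GFP (control) or with Ad-Cre (mutant). Per the labels' protocols, tissue freed of fat was digested with collagenase and trypsin, the infected cells were kept in osteogenic medium for 7 days, complementary DNA was made with SuperScript VILO, and libraries were prepared on an Ion Chef with the Ion AmpliSeq Transcriptome Mouse Gene Expression Panel. Such a panel amplifies 1 short target per gene, so a value measures that target only. It can miss transcripts that lack the target, and a variant under a primer lowers it. The labels do not say whether libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries. For the mutants this spread may be technical. In control 2 alone 18 amplicons stood near 0, which argues against the controls being repeats of the same cells.

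The deposited table gives RPM, the reads of an amplicon scaled to a library total that is equal in all columns, for 23930 amplicons. The aligner, counter, genome build and filters are not given in the sources used here. RPM values divide out the library size and nothing else, so a gene that takes more reads lowers all others slightly. In 27 rows the gene name had been turned into a date, and gene symbols were therefore taken from the amplicon names. A total of 4530 amplicons were at 0 in every library. No row was named Gnas.

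The step between low values gives what 1 read is worth, and 100% of the non-zero values then come out as whole reads within 0.01 read. This gave 18455811 reads in control 1, 13483518 in control 2, 17460018 in mutant 1 and 14847959 in mutant 2. A value of 0 allows up to 3 reads, which is 0.163, 0.222, 0.172 and 0.202 RPM in that order. Intervals and floors cover counting error only, since amplicon reads without molecular identifiers are not independent molecules. A ratio against a group with no read was computed against 3 reads over the group and is a lower bound. With 1 to 3 reads in the lower group the ratio of pooled reads is given with its exact 95% interval.

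Genes with at least 1 RPM in at least 2 libraries were tested (11638). The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(RPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is on the log2(RPM + 1) scale and understates the change of genes with low values, so ratios of mean RPM are given beside it. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 23 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move on balance one way and does not compare the list with other genes.

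The 26 lists were: osteoblast differentiation; Hedgehog ligands, receptors and targets; YAP/TAZ targets; cAMP and CREB-responsive genes; G protein alpha subunits, adenylyl cyclases and protein kinase A; adipogenesis; chondrocyte; tendon; Wnt targets; BMP targets; contractile myofibroblast; collagen matrix; matrix proteases and inhibitors; subcutaneous stromal progenitor; cell cycle; p53 targets; interferon-stimulated genes; inflammatory cytokines and chemokines; hypoxia and glycolysis; and markers of macrophages, lymphocytes, endothelial cells, pericytes, skeletal muscle, keratinocytes, and Schwann cells with melanocytes. Lists share some members, such as Comp in the tendon and chondrocyte lists. The rule for named genes was Gnas, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 10 RPM in the higher group and groups that do not overlap (predicted genes were passed over, and a direction with under 6 was to be filled to 6), then up to 4 members of each list with the smallest unadjusted p. The groups, the test, its alternatives, the lists and this rule were fixed before the data were examined. Some genes that the lists hold are not reported here by name. Genes named outside the rule are marked as chosen after their values were seen.

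The alternatives were a pseudocount of 0.5 or 5, no filter or a filter at 5 RPM, median-of-ratios, TMM or quantile scaling, no trend, a replicate block, each library left out, and count tests on the whole reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Leaving out amplicons near 0 in one control or in both mutants, and leaving out genes on X and Y, were added after seeing the data. Gene positions come from the GENCODE M21 annotation of GRCm38 by symbol (21370 symbols matched) and are those of the gene, not of the amplicon. Tests of positions and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

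The test was checked on simulated reads drawn from these libraries' means, sizes and estimated dispersion, with 200 of 11637 genes changed. In that simulation limma called 10% of genes changed by 2-fold, 80% at 4-fold, 96% at 8-fold and 100% at 16-fold, with 6 false calls among 149. Both simulated groups had the same dispersion, and only genes above a minimum level were changed. The real controls differed from each other far more than the real mutants, so these rates may not hold for these libraries. Camera called 2 of 2 changed lists and 0 of 20 random lists. The simulated reads were drawn with no correlation between genes. The list check therefore cannot tell whether camera's preset correlation is too low for the real lists, and it does not bear on their calls.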

Results

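The study measured messenger RNA in progenitor cells of mouse subcutaneous tissue. The cells came from C57BL/6 mice with a floxed Gnas gene, which encodes the stimulatory G protein alpha subunit that activates adenylyl cyclase. They were infected with an adenovirus carrying either green fluorescent protein (Ad-GFP, the control, genotype wild type) or Cre recombinase (Ad-Cre, genotype Gnas-/-), then kept in osteogenic medium for 7 days. RNA was measured with an amplicon panel that reads each gene through 1 short target. There were 2 control and 2 mutant libraries, called control 1, control 2, mutant 1 and mutant 2. In that order they held 18455811, 13483518, 17460018 and 14847959 reads, computed from the deposited RPM values (reads scaled to a fixed library total). No row of the table was named Gnas, so Gnas itself was not analysed here, and the genotype labels could not be checked by the targeted gene.

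The 2 control libraries differed from each other about as much as from the mutants. Across 11638 tested genes, Pearson's r of log2 values was 0.916 between the controls, 0.981 between the mutants, and 0.885 to 0.909 between a control and a mutant library (correlations across genes, which are not independent replicates). Between the controls 507 genes differed by over 4-fold, against 11 between the mutants. Xist, the noncoding RNA of the inactive X chromosome in females, stood at 165 RPM in control 1, 0 in control 2, 395 in mutant 1 and 419 in mutant 2. The Y-linked gene Ddx3y stood at 61.4, 124, 26.9 and 12.5 RPM in the same order. Control 2 also held the highest macrophage signal, with 822 RPM of the lysozyme gene Lyz2 against 33.9 in control 1, 20.8 in mutant 1 and 10.4 in mutant 2. Xist, Ddx3y and Lyz2 were named after their values were seen.

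The comparison of mutant with control libraries asks how loss of Gnas changes gene expression in these cells under osteogenic conditions. The groups also differ in the virus (Ad-Cre or Ad-GFP), and these libraries cannot tell its effect apart from loss of Gnas. In both mutants Xist was higher and Ddx3y lower than in both controls. Differences between the donors of the cells therefore cannot be told apart from loss of Gnas in general either. In the mutant libraries, the Hedgehog targets Gli1 and Hhip rose from below 0.3 to above 150 RPM. The opioid precursor gene Penk and the imprinted genes Mest, Dlk1, Igf2 and Plagl1 rose by 106-fold to 1680-fold. Matn4 rose as the only 1 of 8 tested chondrocyte genes past the threshold. Fmod was 1 of 2 such genes among 9 tested tendon genes. Eln and Fbn2 were the 2 among 24 tested collagen and matrix genes. Genes that fell included Star, which brings cholesterol into mitochondria, the matrix protease gene Mmp3, the BMP antagonist gene Grem1 and the phosphodiesterase genes Pde3b and Pde4b. In all, 201 genes were higher and 67 were lower in the mutant libraries (limma, adjusted p below 0.05).

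Among the 12 largest rises, Penk went from 1.22 ± 1.72 to 2051 ± 586 RPM (mean ± SD, n = 2 libraries per group here and below), a log2 fold change of 10.08 (SE 0.61, adjusted p = 0.0176). Penk lies on chromosome 4 at 4133531 to 4138819 on the minus strand (GRCm38 annotation of the gene; positions of the amplicons are not given in the sources used here). Mest went from 1.72 ± 2.28 to 654 ± 130 RPM, a 380-fold ratio of means. Dlk1, which encodes a membrane protein that restrains fat cell differentiation, went from 1.59 ± 2.26 to 623 ± 386 RPM. The growth factor gene Igf2 went from 0.362 ± 0.407 to 87.9 ± 65.9 RPM, and Plagl1, which encodes a zinc finger transcription factor, from 0.787 ± 0.0403 to 83.1 ± 6.62 RPM. The choline transporter gene Slc5a7 (189-fold), the protease inhibitor gene Wfdc1 (165-fold) and the BMP antagonist gene Chrdl1 (81.4-fold) belong to the same 12, with Hhip, Gli1, Matn4 and Fbn2, described with their groups.

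Among the 12 largest falls, Star went from 125 ± 40.9 to 1.85 ± 0.62 RPM, a log2 fold change of -5.44 (SE 0.36, adjusted p = 0.0176). It lies on chromosome 8 at 25806555 to 25815982 on the plus strand. Mmp3 went from 419 ± 326 to 7.86 ± 1.55 RPM, and Grem1 from 41.7 ± 8.74 to 2.19 ± 0.143 RPM. Plscr1, a phospholipid scramblase gene, went from 32.3 ± 7.54 RPM to no read in either mutant library, at least 357-fold lower when set against 3 reads over the group. The others were Cyb5r4 (141-fold), Rarb (72.5-fold), Htr2b (61.8-fold), Gngt2 (37.1-fold), Cd53 (33.2-fold), Prdm6 (32.5-fold), Gda (31.8-fold) and Stac2 (23.4-fold). Rarb encodes a retinoic acid receptor, Htr2b a serotonin receptor and Cd53 a tetraspanin of blood cells. Of those at 15 RPM or more in both controls, 7 (Star, Mmp3, Plscr1, Cyb5r4, Gngt2, Cd53 and Gda) stood in both mutant libraries below 5% of their lower control value.

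Of 11 tested members of the list of Hedgehog ligands, receptors and targets, 5 rose, 0 fell and 6 did not pass, and 7 rose when adjusted over the list alone. Hhip, a Hedgehog-binding protein gene induced by the pathway, went from 0.149 ± 0.21 to 220 ± 13 RPM, a log2 fold change of 7.60 (SE 0.29, adjusted p = 0.00472). Gli1, a transcription factor and target of the pathway, went from 0.091 ± 0.024 to 171 ± 17.1 RPM. With 3 control reads its ratio was 1810 (95% counting interval 618 to 8770). The receptor gene Ptch1, itself a target, went from 12 ± 0.554 to 347 ± 60.5 RPM, a 29-fold ratio, and Gli2 from 4.59 ± 1.28 to 56.6 ± 6 RPM, a 12.4-fold ratio. Gli1 lies on chromosome 10 at 127329882 to 127341974 (minus strand), Hhip on chromosome 8 at 79965851 to 80058006 (minus strand) and Ptch1 on chromosome 13 at 63508328 to 63573598 (minus strand). Smo (log2 fold change 0.97, adjusted p = 0.149) and Gli3 (-0.29, adjusted p = 0.694), named after their values were seen, did not pass. The ligand genes Shh, Ihh and Dhh, named on the same ground, stood at or below 0.371 RPM in every library and were not tested. The list ranked above other genes with a median log2 fold change of 1.56 (camera with a preset correlation, adjusted p = 6.65e-06; adjusted p = 0.569 with an estimated correlation). The median was 2.40 without control 1, 1.82 without control 2, 0.94 with no filter on low values and 0.95 with a pseudocount of 5, with a call in each at the preset correlation.

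**Figure D1:**
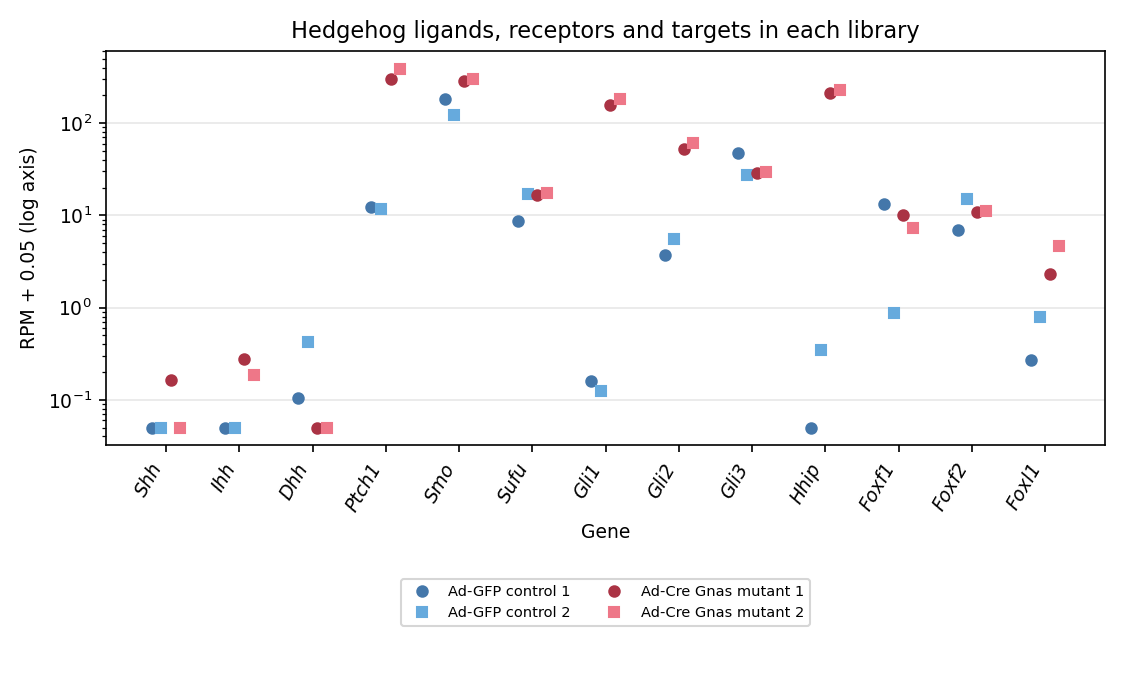
RPM of Hedgehog ligands, receptors and targets in each of the 4 libraries. The vertical axis is logarithmic, 0.05 RPM was added so that zeros can be drawn, and each point is 1 library (blue, Ad-GFP control; red, Ad-Cre Gnas mutant; circles, replicate 1; squares, replicate 2). Gli1 and Hhip lie below 0.3 RPM in both controls and above 150 RPM in both mutants, and the ligands Shh, Ihh and Dhh lie at or below 0.371 RPM throughout.

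Skeletal and matrix lists differed in how far they moved. Of 9 tested tendon genes 2 rose, 0 fell and 7 did not pass, and 5 rose when adjusted over the list alone. These were led by Fmod, a small proteoglycan gene (16 ± 11.4 to 505 ± 112 RPM, 31.6-fold), and Chodl (no read in either control, 6.33 ± 1.33 RPM in the mutants, at least 68.2-fold higher). Tnxb (log2 fold change 1.95, adjusted p = 0.0742) and Comp (3.69, adjusted p = 0.14) did not pass. The tendon list had a median log2 fold change of 2.39 (camera adjusted p = 0.00137, and 0.569 with an estimated correlation). A pseudocount of 5 brought this median to 1.175, with the call kept at the preset correlation. Of 8 tested chondrocyte genes 1 rose, 0 fell and 7 did not pass, and 4 rose when adjusted over the list alone. Matn4, a cartilage matrix protein gene on chromosome 2 at 164389393 to 164405160 (minus strand), went from 2 reads over both controls to 155 ± 10.5 RPM, a ratio of 2460 (95% counting interval 680 to 20300). Matn3 (log2 fold change 2.12, adjusted p = 0.0708) and Col10a1 (no read in the controls, 1.26 and 7.54 RPM in the mutants, adjusted p = 0.206) did not pass. Of the remaining members, Col2a1 stayed below 1 RPM in every library and Acan was at 0 (both named after their values were seen). The chondrocyte list had a median of 1.71 (camera adjusted p = 0.0275; adjusted p = 0.569 with an estimated correlation), and its call ended with no filter on low values (adjusted p = 0.219) or with a filter at 5 RPM (0.108), over a range of 0.00285 to 0.569 across 17 alternatives. Without the filter the median was 0.04.

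Of 24 tested collagen and matrix genes 2 rose, 0 fell and 22 did not pass, and 8 rose when adjusted over the list alone. The elastin gene Eln went from 0.761 ± 0.762 to 53.6 ± 32.4 RPM and the fibrillin gene Fbn2 from 3.95 ± 4.53 to 163 ± 50.2 RPM. Col6a1 (1001 ± 330 against 3642 ± 128 RPM, adjusted p = 0.0702) and Lum (log2 fold change 1.45, adjusted p = 0.0948) did not pass. The list's median was 0.80 (camera adjusted p = 0.00362; adjusted p = 0.569 with an estimated correlation). Without control 1 its call ended (median 0.67, adjusted p = 0.15, over a range of 5.05e-06 to 0.569 across 17 alternatives). Of 20 tested matrix proteases and inhibitors 1 rose (Adamts1, 119 ± 5.05 to 587 ± 87.8 RPM), 1 fell (Mmp3) and 18 did not pass. When adjusted over the list alone, 2 rose and 3 fell. Adamts2 (log2 fold change -1.61, adjusted p = 0.0941) and Mmp12 (-2.76, adjusted p = 0.104) did not pass. The protease list had a camera adjusted p of 0.0738.

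Of 15 tested osteoblast differentiation genes only Dlx5 rose, 0 fell and 14 did not pass, and 2 rose when adjusted over the list alone. Dlx5, a homeobox gene of skeletal development, went from 0.296 ± 0.419 to 42.9 ± 3.02 RPM (adjusted p = 0.0176). Runx2, the master regulator of bone-forming cells, stood at 37.7 ± 3.83 and 67.2 ± 10 RPM (log2 fold change 0.81, adjusted p = 0.175), and Omd at 0.19 ± 0.268 and 3.79 ± 0.739 RPM (adjusted p = 0.0747). Spp1, which bone cells and macrophages both express and which was named after its values were seen, stood at 906 RPM in control 1 and 17340 in control 2, the library with the most Lyz2, against 312 and 216 in the mutants (adjusted p = 0.232). The osteoblast list had a median of 0.91 (camera adjusted p = 0.0559; adjusted p = 0.638 with an estimated correlation).

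**Figure D2:**
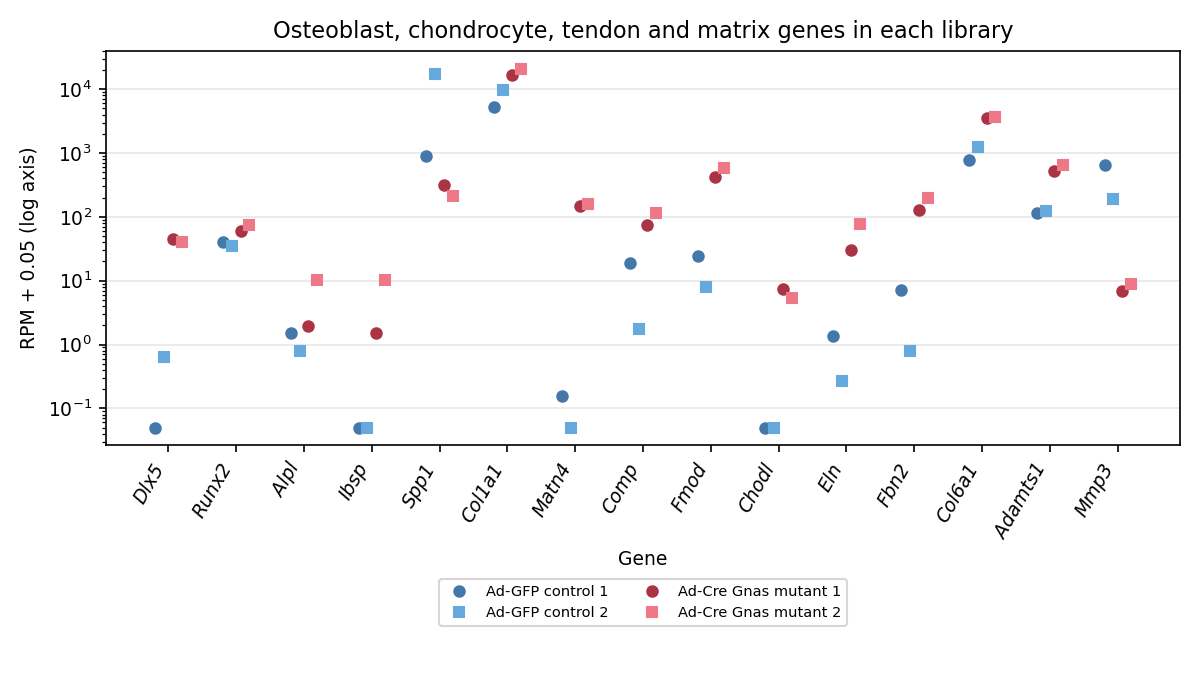
RPM of osteoblast, chondrocyte, tendon and matrix genes in each library, on a logarithmic axis with 0.05 RPM added; each point is 1 library (blue, control; red, mutant; circles, replicate 1; squares, replicate 2). The groups do not overlap for Dlx5, Matn4, Fmod, Eln, Fbn2 or Spp1, which also holds for 51.8% of all tested genes. Spp1 spans 906 to 17340 RPM between the 2 controls, against 312 and 216 in the mutants.

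Few members of the fixed lists tied to cyclic AMP, the product of the enzyme that Gnas activates, passed the threshold. These lists do not hold every gene that responds to cyclic AMP. Camera looks for a shift of a whole list upwards or downwards, so it can miss a list whose members move both ways. Of 17 tested cAMP and CREB-responsive genes 0 rose, 2 fell and 15 did not pass. When adjusted over the list alone, 1 rose and 3 fell. Pde3b went from 36.8 ± 0.67 to 3.25 ± 0.504 RPM (adjusted p = 0.0211) and Pde4b from 26.3 ± 12.3 to 2.52 ± 0.894 RPM (adjusted p = 0.0491). Both encode enzymes that break down cyclic AMP. Pde7b (log2 fold change -1.53, adjusted p = 0.0948) and Rgs2 (3.01, adjusted p = 0.121) did not pass, nor did the list (camera adjusted p = 0.148). None of 23 tested G protein alpha subunit, adenylyl cyclase and protein kinase A genes passed at the threshold or when adjusted over the list alone (limma; camera adjusted p = 0.971). The nearest were Gnao1 (log2 fold change 1.31, adjusted p = 0.125), Adcy1 (3.16, adjusted p = 0.13), Prkar1b (-1.03, adjusted p = 0.146) and Gnai1 (1.99, adjusted p = 0.163).

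Other signalling lists did not pass as lists, though single members did. Of 22 tested YAP/TAZ targets only Ccdc80 rose, also when adjusted over the list alone (278 ± 48.8 to 1109 ± 162 RPM). The 21 others did not pass, among them Arhgef17 (log2 fold change 1.08, adjusted p = 0.0963), Ptpn14 (0.94, adjusted p = 0.152) and Asap1 (1.32, adjusted p = 0.153). The YAP/TAZ list had a camera adjusted p of 0.227. Of 9 tested Wnt targets only Lgr5 rose, also when adjusted over the list alone (0.271 ± 0.383 to 16.3 ± 4.83 RPM). The 8 others did not pass, with Nkd1 and Dkk2 at adjusted p = 0.206 and 0.262. The Wnt list had a camera adjusted p of 0.233. None of 10 tested BMP targets passed, also when adjusted over the list alone, with Bambi nearest (log2 fold change 1.51, adjusted p = 0.142; list camera adjusted p = 0.991). Of 21 tested p53 targets only Sesn1 rose (4.62 ± 0.487 to 20 ± 0.607 RPM) and 20 did not pass. When adjusted over the list alone, 2 rose and 1 fell. Fas (log2 fold change 1.57) had an adjusted p of 0.0792 over all genes, and the p53 list one of 0.675.

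Of 14 tested contractile genes only the myosin kinase gene Mylk rose, also when adjusted over the list alone (4.22 ± 0.531 to 23.4 ± 5.13 RPM). Cnn2 (adjusted p = 0.236) and Myl9 (0.312) were among the 13 that did not pass. The contractile list had a camera adjusted p of 0.083. Of 14 tested markers of subcutaneous stromal progenitors only Dpt, a dermal matrix protein gene, rose, also when adjusted over the list alone (38.5 ± 27.7 to 548 ± 167 RPM). The 13 others did not pass, with Col15a1 at a log2 fold change of -2.49 (adjusted p = 0.142). The progenitor list had a camera adjusted p of 0.233. None of 15 tested adipogenesis genes passed over all genes, and 1 fell when adjusted over the list alone. Cebpb stood nearest (293 ± 55.5 against 119 ± 0.74 RPM, adjusted p = 0.0643). The adipogenesis list had a median of -0.18 and a mean of 0.17, and camera placed it upwards (adjusted p = 0.991). None of 25 tested cell cycle genes passed, also when adjusted over the list alone (camera adjusted p = 0.983, placed downwards against a median of 0.17). Their median lay 1.21 above control 1 and -0.74 from control 2 on the log2 scale, and Rrm2 (0.84, adjusted p = 0.538) and Mki67 (0.59, adjusted p = 0.718) did not pass.

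Hypoxia and glycolysis genes ranked lower in the mutants. Of 15 tested members 0 rose, 1 fell and 14 did not pass, and 4 fell when adjusted over the list alone. Hk2, the gene of a hexokinase that starts glycolysis, went from 138 ± 43.3 to 36.7 ± 2.05 RPM (adjusted p = 0.0477). Vegfa (416 ± 294 against 56.5 ± 16.4 RPM, adjusted p = 0.0941), the glucose transporter gene Slc2a1 (294 ± 240 against 34.5 ± 1.15 RPM, adjusted p = 0.109) and P4ha2 (adjusted p = 0.122) did not pass. The list's median was -1.60 (camera adjusted p = 9.61e-06; adjusted p = 0.638 with an estimated correlation). Control 2, the library with 822 RPM of Lyz2, set much of this size: the median was -2.26 without control 1 and -0.52 without control 2.

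Of 18 measured macrophage markers 8 reached the filter, and none of the 8 passed over all genes or when adjusted over the list alone. As a list they ranked lower (median -2.70, camera adjusted p = 0.00135, and 0.638 with an estimated correlation). A marker near 0 in both mutants reaches the filter only if both controls hold at least 1 RPM, so its direction was fixed beforehand. With no filter the median was -0.968. With a filter at 5 RPM 2 markers were left and the list was not tested. Cd68 stood at 6.12 and 57.7 RPM in the controls and at 3.04 and 2.16 in the mutants, and Tyrobp at 1.35, 24.9, 0.115 and 0 RPM. Ctss and Fcer1g had adjusted p = 0.225 and 0.281. The median was -4.33 without control 1 and -1.06 without control 2. Of 13 tested inflammatory cytokine and chemokine genes 1 rose (Cxcl12, 208 ± 16.3 to 569 ± 5.53 RPM), 1 fell (Ptgs2, 131 ± 54.2 to 23.4 ± 0.561 RPM) and 11 did not pass. When adjusted over the list alone, 1 rose and 2 fell. The inflammatory list had a camera adjusted p of 0.148. Ptgs2 stood at 92.4 RPM in control 1 and at 169 in control 2, the library with the most Lyz2. None of 22 tested interferon-stimulated genes passed, also when adjusted over the list alone, with Irf7 (log2 fold change -1.53, adjusted p = 0.0948) nearest and a list adjusted p of 0.0658.

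Markers of other cell types of subcutaneous tissue were low or mixed. Of 5 tested pericyte markers 2 rose (Cspg4, 18.5 ± 4.87 to 134 ± 32.6 RPM, and Notch3, 14.4 ± 4.9 to 92.3 ± 17 RPM), 3 did not pass and 3 rose when adjusted over the list alone. Ndufa4l2 stood at 504 RPM in control 2 against 6.7 to 9.77 in the other libraries (list adjusted p = 0.0658, median 2.58, mean 1.03). Of 9 tested endothelial markers 1 rose (Flt1, 8.86 ± 1.42 to 46.3 ± 7.09 RPM), 8 did not pass and 3 rose when adjusted over the list alone (list adjusted p = 0.233). None of 6 tested skeletal muscle markers passed and 2 rose when adjusted over the list alone (Tnnt3 adjusted p = 0.119; list adjusted p = 0.233). Of the 11 measured lymphocyte markers 0 reached the filter, and of 13 keratinocyte markers only Sfn did (adjusted p = 0.824). Of 13 Schwann cell and melanocyte markers 4 reached it, and 1 of these rose when adjusted over the list alone. S100b (1.99 ± 1.28 against 13.9 ± 1.37 RPM, adjusted p = 0.066) and the other 3 did not pass over all genes. Lists with under 5 tested members had no list test.

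**Figure D3:**
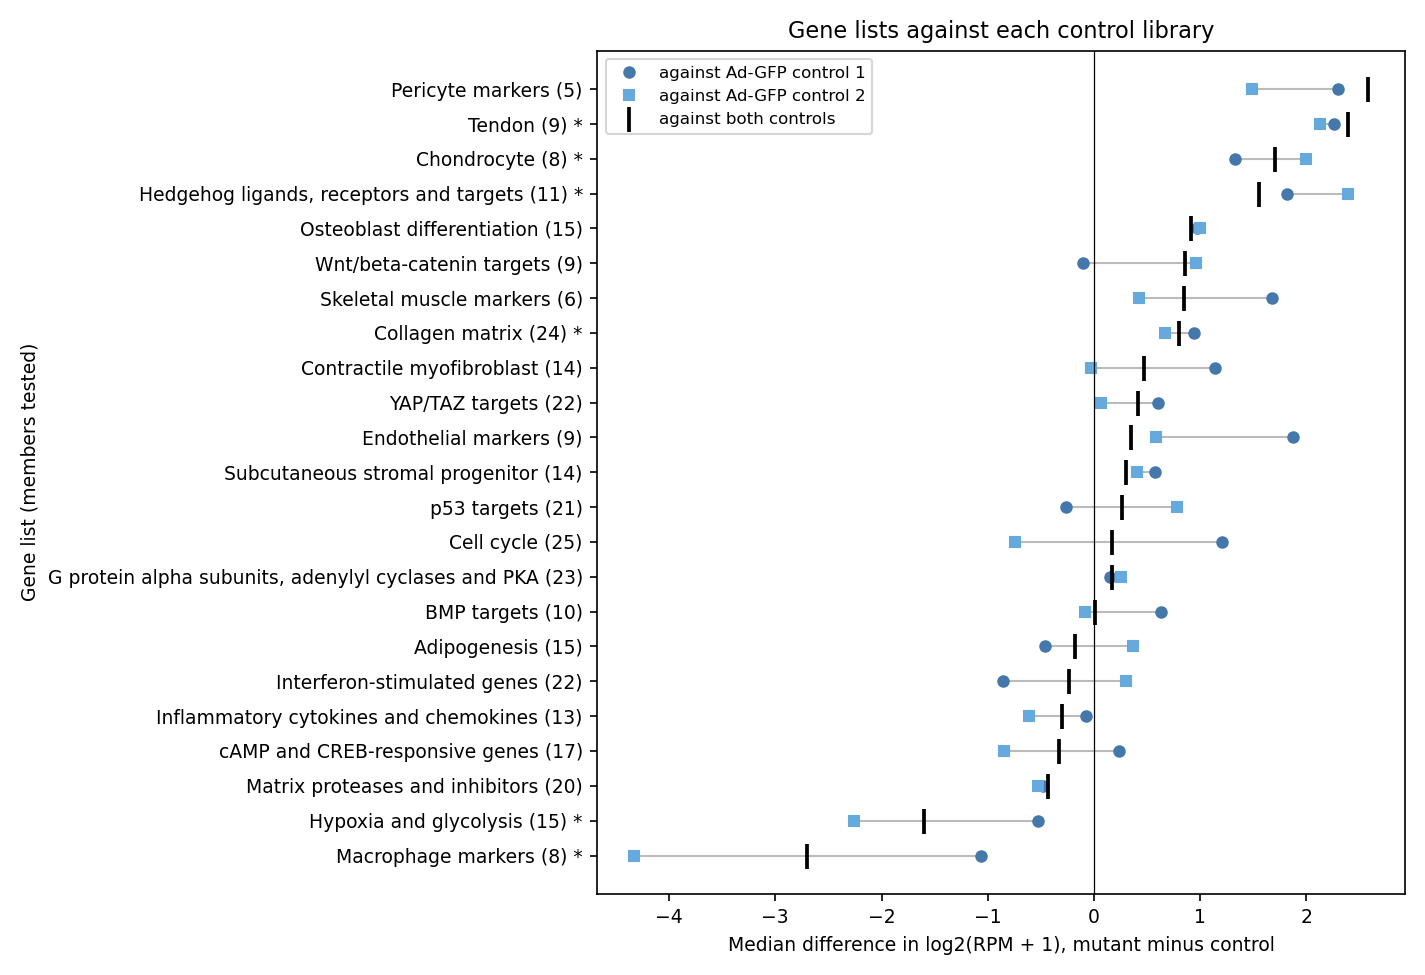
Median difference in log2(RPM + 1) over the tested members of each of 23 gene lists, mutant mean minus control (horizontal axis), taken against control 1 (dark circles), control 2 (light squares) and both (black bars). The number of tested members stands in parentheses and a star marks an adjusted p below 0.05 by camera with a preset correlation. The macrophage list lies at -1.06 against control 1 and -4.33 against control 2, and the cell cycle list at 1.21 and -0.74.

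Of 23 lists tested, 4 ranked higher (Hedgehog, tendon, chondrocyte, collagen matrix) and 2 lower (hypoxia and glycolysis, macrophage) by camera with a preset correlation. With an estimated correlation 0 of these calls held (adjusted p = 0.569 for the 4 higher lists and 0.638 for the 2 lower ones). The count of called genes rests on the libraries used: limma called 0 genes without mutant 1 (805 at an unadjusted p under 0.05) and 0 without mutant 2 (777), 1609 higher and 802 lower without control 1, and 1065 and 794 without control 2. On whole reads of all 4 libraries edgeR called 64 higher and 24 lower, without Penk, Mest, Dlk1, Igf2, Dlx5, Fmod, Eln, Fbn2, Mmp3, Pde4b and Hk2 among others, and DESeq2 called 591 and 500.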

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

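The alternatives without X and Y genes and without amplicons near 0 were chosen after the results were seen. The main counts were 201 genes higher and 67 lower, and 4 lists higher and 2 lower. With no filter on low values limma called 56 and 18 genes, all shared with the main calls, and 4 lists lower; more genes are then tested. With edgeR's quasi-likelihood test on whole reads 64 genes were higher and 24 lower, all shared, and with no filter 795 and 825. DESeq2 called 591 and 500, of which 197 and 67 were shared. The replicate numbers share only a number in the labels, and replicate 1 minus replicate 2 correlated at 0.164 between the groups across genes. A replicate block gave 301 genes higher and 123 lower, 7 lists higher and 4 lower, and edgeR with the replicate block 50 and 22 genes. With a filter at 5 RPM 1 list was lower, since 2 macrophage markers were then left to test. Quantile scaling shifted the median of all genes by -0.11 on the log2 scale and called 7 lists higher, and Sfn then stood at -0.009 (0.25 in the main test). With an estimated correlation camera called 0 lists higher and 0 lower, and fry 2 higher (Hedgehog and chondrocyte) and 0 lower. A pseudocount of 5 or no filter lowered the Hedgehog median to 0.95 and 0.94 and kept its call. A pseudocount of 5 also brought the tendon median to 1.175, and no filter the macrophage median to -0.968, with these calls kept. For edgeR, DESeq2, the block, quantile scaling, camera with an estimated correlation and fry the cause was not tested. Leaving out one replicate at a time, where a lone library is assumed to vary like the other group, gave 0 to 1609 genes higher and 0 to 802 lower, and 4 to 12 lists higher and 2 to 6 lower. Without either mutant library the spread comes from the 2 controls alone, which differ widely, and limma then called 0 genes (805 and 777 at an unadjusted p under 0.05). Without control 1 it called 1609 higher and 802 lower, and without control 2 1065 and 794, which include all 201 and 67 main calls. Under these fits some genes that did not pass in the main test changed sign: without control 1 Rrm2 (range of log2 fold change with one library left out -0.088 to 1.77), Mki67 (-0.45 to 1.62) and Mlana (-4.16 to 1.54), without control 2 Tyms (-1.48 to 0.33) and Cdc20 (-1.80 to 0.52), and without control 2 or mutant 2 Sfn (-0.24 to 0.75). Other pseudocounts, a filter at 5 RPM, other scaling and no trend gave 175 to 219 genes higher and 49 to 94 lower, without X and Y genes 194 and 63, and without near-zero amplicons 213 and 64. Of 44 named genes past the threshold, 13 stayed past it in every alternative that kept all libraries and tested them, among them Gli1, Gli2, Hhip, Ptch1, Matn4, Plagl1 and Pde3b, which all of these alternatives tested. Star, Cd53, Gda and Plscr1 are among the 13 but were not tested without near-zero amplicons. No alternative left out amplicons for being near 0 in both controls, as those of Gli1, Hhip and Matn4 were. Of the 44, 0 changed sign in any alternative that tested them. No list's median moved in its second decimal when members with no read in one group were set at their bound. Depth sets 3 reads at 0.163 to 0.222 RPM, so differences near or below that level, as for the Hedgehog ligands, were not detectable.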

Other observations

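The gene lists of this part, the genes it names outside the rule and its tests of explanations (near-zero and partly lowered amplicons, macrophage RNA, female share, dividing cells) were chosen after the results were seen, and the bound for partly lowered amplicons was set after their count was known. Some imprinted genes with roles in growth were among the rises. Of 18 tested imprinted genes 9 rose, 0 fell and 9 did not pass, and 15 were above both controls in both mutants. Over all 11638 tested genes the groups did not overlap, in either direction, for 51.8%, against 33.3% by chance for 2 against 2. Besides Mest, Dlk1, Igf2 and Plagl1, the zinc finger gene Peg3 went from 8.94 and 5.04 RPM in the controls to 165 and 168 in the mutants, the cell cycle inhibitor gene Cdkn1c from 6.67 and 5.71 to 45.1 and 87.4, Zim1 from 0.921 and 0.074 to 14.3 and 12.7, and the noncoding Meg3 from 353 and 492 to 1539 and 1393. H19, at 3.09 and 43.2 against 355 and 1189 RPM, did not pass (limma adjusted p = 0.102). The list's median log2 fold change was 1.70 (camera adjusted over 4 such lists, 1.26e-10; adjusted p = 0.0752 with an estimated correlation). Because the list was drawn up from genes seen among the calls, its p is not independent evidence.

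Axon guidance genes moved in both directions. Of 27 tested members 4 rose, 1 fell and 22 did not pass (camera adjusted p = 0.13). Sema3f went from 12 and 7.79 RPM in the controls to 128 and 182 in the mutants, the netrin gene Ntn1 from 9.86 and 8.08 to 66.6 and 90.3, the semaphorin co-receptor gene Nrp1 from 67 and 51.4 to 300.5 and 268, and Sema3c from 3.31 and 3.19 to 18.6 and 15.1, while Sema3e fell from 19.5 and 15.5 to 2.75 and 3.44. None of 20 tested genes of the ATF4 and amino acid response passed (limma), though the list ranked lower (median -0.70, camera adjusted p = 6.99e-05; adjusted p = 0.554 with an estimated correlation); without control 1, where Ddit3 stood at 1390 RPM against 170, 179 and 111, camera gave p = 0.211. None of 18 tested cholesterol synthesis genes passed, and that list lay -0.42 from control 1 and 1.45 above control 2 (camera adjusted p = 0.159).

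In control 2, 18 amplicons that stood at 15 RPM or more in the other 3 libraries were below 5% of that level, among them Cox7a2, Galnt10, Ppfibp1, Elovl5 and Lta4h. Too few reads are argued against, since the lowest level elsewhere would give at least 211 reads in control 2. Of the 16 with an autosomal position, 10 lay within 5 Mb of another, against a mean of 1.4 in 10000 random sets of genes (permutation p = 0.0003), which is consistent with variants under the amplicons carried in linked blocks by the donor. Control 1 showed no such clustering among its 6 near-zero amplicons (0 within 5 Mb of another, mean of random sets 0.19, permutation p = 1), a number too small to decide. A further test on 42 amplicons only partly lowered in control 2 found 3 within 5 Mb of a near-zero one, no more than the 3.47 of random sets (permutation p = 0.686), so it decides nothing. The 7 amplicons below 5% in both mutants, among those at 15 RPM or more in both controls and all among the 12 largest falls, showed 0 within 5 Mb of another, and a donor variant under single amplicons such as Plscr1 or Cyb5r4 stays open next to an effect of Gnas loss, as the labels do not name the donors. Amplicons near 0 in both controls, such as those of Gli1, Hhip and Matn4, were not searched for in this way. The same question was therefore not tested for the rises.

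Whether the lower macrophage list comes from control 2 alone stays open. Without that library the median was -1.06 (camera adjusted p = 0.0298, over a range of 3.26e-09 to 0.638 across 16 alternatives). Most of the size was then lost, control 1 was the only control left, and with all libraries the call ended with an estimated correlation (adjusted p = 0.638) and with fry (adjusted p = 0.416). The filter was applied before control 2 was left out. Markers near 0 in both mutants were thus still those with at least 1 RPM in both controls. Summed over the markers, macrophage signal was 52.2 RPM in control 1, 1039 in control 2, 30.2 in mutant 1 and 17 in mutant 2. If macrophage RNA carried the hypoxia and glycolysis genes too, their excess over the mutants in control 1 should be as small a part of that in control 2 as for the macrophage markers, where the median was 5% (quartiles 2.1 to 7.6). It was 19.2% (quartiles -1 to 28), so the spread is too wide to decide. Lower oxygen or denser culture in control 2 was not tested, and neither was an effect of Gnas loss on these genes apart from the library.

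The rises of Hedgehog and imprinted genes might reflect a larger female share of the cells in the mutant libraries, since Xist in control 1 was 40.5% of its mean in the mutants and 0 in control 2. Control 1 should then lie about that far on the way from control 2 to the mutants, but the median was 0.2% of the way over the 11 tested Hedgehog genes and 3.7% over the imprinted genes. The upper quartiles were 95.7 and 41.6, so the spread over the whole lists is too wide to decide. Among the members past the threshold, however, control 1 lay close to control 2, or below it, when set against the mutant level. Controls 1 and 2 stood at 0.108 and 0.074 RPM for Gli1, 12.4 and 11.6 for Ptch1, 0.108 and 3.34 for Mest, and 8.94 and 5.04 for Peg3. These values argue against this explanation for the members that passed. Agreement between the controls helps a gene to pass, so the explanation stays open for the other members. A larger share of dividing cells is argued against for the imprinted genes, because the mutants lay between the controls in cell cycle genes (24 of 25 higher than in control 1, 1 of 25 higher than in control 2), whereas of 18 imprinted genes 16 were higher than in control 1 and 16 higher than in control 2, though not the same 16. Donor age, other differences between donor pools, the virus used (Ad-Cre or Ad-GFP) and the loss of Gnas itself were not tested and are confounded in these 4 libraries.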
